A study of Mus musculus with 10 samples.

How the data were processed

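RNA bound to Musashi1 and Musashi2, a pair of RNA-binding proteins, was recovered from mouse pituitary by immunoprecipitation and sequenced. Per the labels, each lysate came from 6 pituitaries of sighted FVB mice aged 8 to 10 weeks and was divided equally between the pooled Musashi1 and Musashi2 antibodies (Musashi IP) and control rabbit IgG. Libraries were made with the TruSeq Stranded Total RNA Gold kit, which removes ribosomal RNA and keeps strand. The 10 libraries used here came from 5 lysates, numbered 2, 5 and 6 (female) and 3 and 7 (male). The protocol speaks of 6 occasions, 3 per sex; a further male pair was not analysed here. The immunoprecipitations were done on separate occasions, so the lysates of a sex are taken as separate sets of mice.

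The authors deposited a table of raw read counts per Ensembl gene, with no normalization, in whole numbers for 55416 genes. FastQC 0.11.8, Trimmomatic 0.39, STAR 2.7.1a and the genome build GRCm39 are named, per the submitters' processing notes. The program that counted reads, the gene annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes that share sequence with a close copy (such as Hbb-bs and Hbb-bt, the globin and histone families, and mitochondrial genes with nuclear copies) are therefore uncertain. The same holds for small RNAs inside other genes and for genes that overlap a neighbour on the opposite strand, such as Pard3bos1.

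Gene symbols, biotypes and sequences were taken by Ensembl gene ID from GENCODE release M21 on GRCm38, an older build than that of the counts, so no coordinates are given. Of the gene IDs, 52083 (94.0%) had a match. IDs with no match held between 0.741% and 4.05% of a library's counts and stayed in the library totals and tests. Biotypes were grouped into protein-coding, long noncoding, TEC (loci that the annotation marks as still lacking experimental evidence), pseudogene, small noncoding and mitochondrial genes.

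Library totals ran from 6.67 to 13.0 M counts, so 1 count in the shallowest library equals 0.150 CPM. No molecular identifiers are described in the sources used here, so counts are not independent molecules. No pair of libraries held identical values, and the highest correlation of log CPM between any of them was 0.982.

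All tests ran on the counts as deposited, in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by edgeR's filterByExpr, libraries were scaled by TMM factors (trimmed mean of M values), and the quasi-likelihood test (glmQLFit, glmQLFTest) was used with Benjamini-Hochberg adjustment at 0.05. Musashi IP was compared with IgG over all 10 libraries with the lysate as a block (4 residual degrees of freedom, 20550 genes tested). The antibody effect nested in sex, and the female minus male difference of that effect, were fitted the same way with 3 residual degrees of freedom. Females and males were compared, unpaired, within the 5 IgG libraries and within the 5 Musashi IP libraries. The SE of a log2 fold change is its size divided by the square root of the test's F value. CPM (counts scaled by library size) are given as mean ± SD over libraries, after TMM scaling, and log2 ratios of single lysates were computed with a prior count of 2.

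The lysate number pairs the libraries because the protocol says that each lysate was split. Deviations from the group means of libraries with the same number correlated at 0.523, 0.679, 0.602, 0.186 and 0.778 for lysates 2, 3, 5, 6 and 7. In 4 of the 5 lysates this was above the highest correlation of the lysate's IgG library with a Musashi IP library of another number. In lysate 6 it was below that value (0.415).

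These choices, the gene lists and the rule for named genes were fixed before the data were examined. Named for the antibody comparison were the 10 enriched and 10 lower genes of largest fold change with adjusted p under 0.05, at least 8 CPM on average, the same sign in all 5 pairs and an approved symbol. Msi1, Msi2, all known Musashi targets and all pituitary hormones were added, with up to 4 members past the threshold from each other list. For comparisons between sexes the rule took 5 genes per direction, Xist and 4 Y-linked genes, and, where fewer than 3 genes passed, the 5 of smallest unadjusted p. Other genes in the text were chosen after their values were seen. The 32 gene lists covered known Musashi targets, hormones, receptors, transcription factors, markers of pituitary and other cell types, signalling pathways and RNA classes. A list with at least 5 tested members (28 lists) was tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted by Benjamini-Hochberg over the lists.

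Musashi motifs, (G/A)U1-3AGU, were counted in the longest annotated 3' UTR (untranslated region) of each tested gene, at a minimum of 100 nt. Enriched genes were compared with other tested genes in strata of 3' UTR length, GC content and mean expression by a two-sided permutation test with 100000 resamples. This part used Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

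Each procedure was tested on simulated counts with 100 genes changed per fold size. For Musashi IP versus IgG the test found 17% of genes changed 1.5-fold and 98% of genes changed 3-fold, and called 6 unchanged genes in a run of 20550 genes. For 3-fold changes it found 89% in females, 67% in males, 35% for the difference between sexes, 77% between sexes in IgG and 47% between sexes in Musashi IP. Simulated changes went up and down in equal number. Changes as many and as one-sided as those of the real antibody comparison were not simulated, so its error rate is not known from this. Camera at the preset correlation found 3 of 3 raised lists and called 1 other list. The estimated correlation and fry found 3 and called 0 others. Simulated genes were drawn independently and put into lists at random, while the estimated correlation within the real lists reached 0.960. The simulation therefore does not show how well these tests find lists of correlated genes. A true motif difference of 0.3 per kb was returned as 0.268.

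The alternatives tried were DESeq2 size factors, library totals alone, DESeq2 1.42.0, limma-voom with quality weights, no filter on low counts and a filter at 2 CPM. Further ones left out mitochondrial and small noncoding genes, dropped the lysate block, corrected for length and GC content with loess offsets, and left out each lysate or library in turn. A fit on protein-coding genes only was added after the data were seen.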

Results

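Musashi1 and Musashi2 are RNA-binding proteins that recognise short motifs, mainly in the 3' UTRs of mRNAs, and regulate their translation. The study asked which pituitary RNAs they bind, by sequencing RNA that came down with pooled Musashi1 and Musashi2 antibodies (Musashi IP) and with control rabbit IgG from the same lysates. There were 10 libraries from 5 lysates of 6 mouse pituitaries each, with 3 lysates from females (2, 5 and 6) and 2 from males (3 and 7). The table held raw counts for 55416 genes. IgG libraries had 7.62 ± 1.08 M counts and Musashi IP libraries 10.4 ± 1.89 M (mean ± SD, n = 5 each). The shallowest was IgG 3, with 6.67 M counts, and the deepest Musashi IP 6, with 13.0 M.

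The sex labels matched sex-linked RNAs in every library. Xist, the noncoding RNA that silences an X chromosome in females, had 29638 to 70049 counts in the 6 female libraries and 34 to 56 in the 4 male ones. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had 0 or 1 count in each female library and between 854 and 2217 in each male library.

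Protein-coding genes held 81.3 ± 1.29% of counts in IgG and 87.0 ± 2.97% in Musashi IP, and were higher in 5 of 5 pairs. Long noncoding RNA held 11.01 ± 0.808% of counts in IgG and 8.05 ± 1.57% in Musashi IP, and TEC loci 2.85 ± 0.505% and 1.86 ± 0.436%. Malat1, a nuclear long noncoding RNA, held 4.90 ± 0.521% of counts in IgG and 3.41 ± 0.988% in Musashi IP. Each of these shares moved the same way in all 5 pairs, for which the exact sign-flip test gave p = 0.0625, the smallest value 5 pairs allow (two-sided, 0.0833 after Benjamini-Hochberg adjustment over 12 measures). Mitochondrial genes held 0.934 ± 1.05% and 0.777 ± 0.528% of counts, and were lower in 3 of 5 pairs (exact p = 0.812). The IgG mean rests on IgG 2, with 2.77% against 1.54% in Musashi IP 2; in lysates 3, 5, 6 and 7 the shares were 0.798, 0.301, 0.210 and 0.593% in IgG and 1.10, 0.270, 0.432 and 0.541% in Musashi IP, higher in 2 of these 4 pairs.

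Among genes with an approved symbol, at least 8 CPM on average and the same sign in all 5 pairs, those most enriched over IgG were Tmem167b, which encodes a small membrane protein, at 7.35-fold (log2 2.88 ± 0.33, mean ± SE, n = 5 lysates), and Tgoln1, which encodes a protein of the trans-Golgi network, at log2 2.83 ± 0.33. Tmem167b rose from 29.2 ± 9.51 to 247 ± 175 CPM (counts scaled by library size, SD). Next came the Mediator subunit gene Med22 (2.76 ± 0.23), Tmem30b (2.74 ± 0.37), Tmem130 (2.71 ± 0.25), the actin-binding protein gene Cotl1 (2.69 ± 0.31) and Sumo3 (2.69 ± 0.28), which encodes a ubiquitin-like modifier. Timm29 (2.69 ± 0.23), the long noncoding RNA Dbpht2 (2.64 ± 0.26) and the ubiquitin-conjugating enzyme gene Ube2l3 (2.60 ± 0.27) completed the top 10. All 10 were higher in 5 of 5 lysates, and their largest adjusted p was 0.00354 (edgeR, Benjamini-Hochberg). By the same rule, the 10 RNAs lowered most were the small nucleolar RNAs Snord15a (-0.97 ± 0.15) and Snord17 (-0.86), Tex47 (-0.82), Xist (-0.81 ± 0.11), the beta-globin mRNAs Hbb-bs (-0.79 ± 0.14) and Hbb-bt (-0.75 ± 0.20), Pard3bos1 (-0.74 ± 0.13), the microRNA genes Mir384 (-0.73 ± 0.14) and Mir335 (-0.67 ± 0.12), and Hs3st5 (-0.71 ± 0.15), a heparan sulfate sulfotransferase gene. Without the lysate block Snord15a, Hbb-bs, Hbb-bt, Mir384 and Mir335 lost their calls (adjusted p = 0.0646, 0.0965, 0.191, 0.0762 and 0.219, edgeR), and after the length and GC correction so did Snord15a, Hbb-bt, Mir384 and Mir335 (0.117, 0.0923, 0.983 and 0.654), with log2 values of -0.43, -0.55, -0.0069 and -0.077, while Snord17 stood at -0.48. Hbb-bt also lost its call without lysate 2, 5 or 7 (0.0597, 0.103 and 0.0629) and Hs3st5 without lysate 5 or 7 (0.0624 and 0.0512).

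In all, 5531 of 20550 genes tested differed, 3804 enriched in Musashi IP and 1727 lower (edgeR with the lysate block, Benjamini-Hochberg 0.05), against 8653 at an unadjusted p under 0.05. Of the enriched genes, 1452 were higher by 2-fold or more and 146 by 4-fold or more, while 56 genes were lower by 2-fold or more. Enriched genes had a median of 1.81-fold, and 3622 of them were higher in all 5 pairs; genes in the other direction had a median of 0.687-fold. The split by direction follows the scaling: with library totals alone, which shift the median log2 fold change of all genes by -0.18, 3149 genes were enriched and 4107 lower. Without the lysate block 3312 genes were enriched and 670 lower, of which 3267 and 662 were also called with it, and without lysate 5 or lysate 7 the total fell to 2897 or 2885.

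Most enriched genes were protein-coding. Of 14193 protein-coding genes 3650 rose and 569 fell, with a median log2 fold change of 0.09 that became -0.09 under library totals. Of 1725 TEC loci 15 rose and 592 fell (median -0.44), of 1302 pseudogenes 27 rose and 154 fell (-0.38), and of 350 small noncoding RNAs 1 rose and 70 fell (-0.46). Long noncoding RNAs had 105 higher and 298 lower of 2692, with a median of -0.28. These noncoding medians lay below 0 in all 5 lysates and under each scaling. Of 11 mitochondrial genes 6 rose and 1 fell, with a median of 0.69 that lay above 0 in 5 of 5 lysates. Their summed share of counts was nonetheless lower in 3 of 5 pairs.

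**Figure D1:**
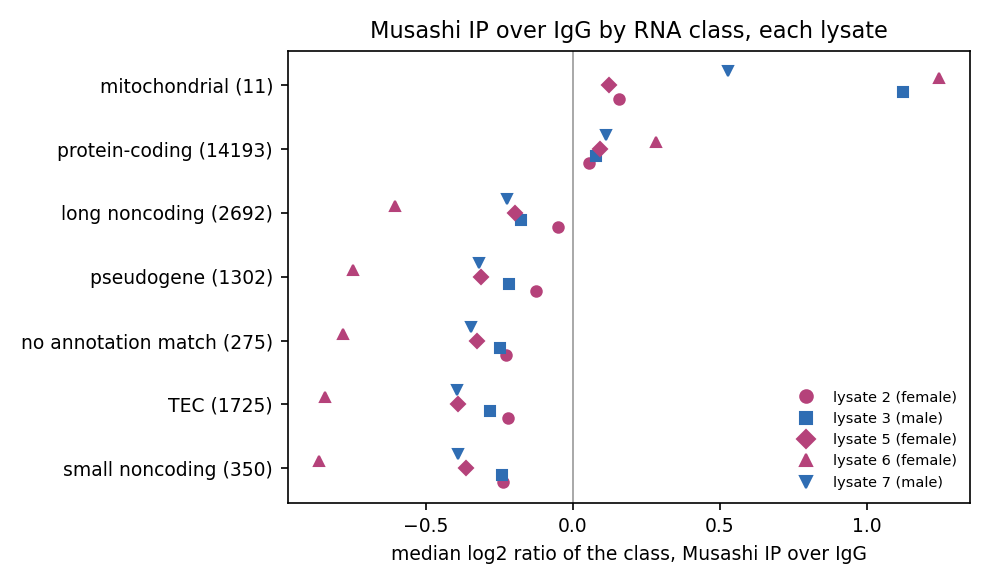
Median log2 ratio of Musashi IP over IgG (horizontal axis) for each RNA class (number of genes tested in brackets), with 1 point per lysate, coloured by sex. In each of the 5 lysates the protein-coding and mitochondrial medians lie above 0. Those of long noncoding RNAs, pseudogenes, TEC loci, small noncoding RNAs and unmatched genes lie below 0. Under library totals the protein-coding median over all lysates is -0.09.

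Both Musashi mRNAs were themselves enriched, Msi1 at 1.53-fold (log2 0.61 ± 0.13) and Msi2 at 1.70-fold (0.76 ± 0.15), each in 5 of 5 lysates. Of 16 tested mRNAs known as Musashi targets from other work, 9 rose, 0 fell and 7 did not pass. The largest was Fshb, the beta subunit of follicle-stimulating hormone, at 4.86-fold (2.28 ± 0.37; 84.1 ± 73.8 to 431 ± 337 CPM), followed by the gonadotropin-releasing hormone receptor Gnrhr at 3.06-fold (1.61 ± 0.23; 48.0 ± 6.97 to 156 ± 61.7). Others that rose included the cell cycle inhibitor Cdkn1a (1.15 ± 0.26), the TGF-beta receptor Tgfbr1 (0.97 ± 0.20), Mapt (0.58 ± 0.10), Dcx (0.58 ± 0.15), Smad3 (0.57 ± 0.13) and the Notch inhibitor Numb (0.57 ± 0.11). Among those that did not pass were Pou1f1 (0.22 ± 0.10), a transcription factor of somatotropes, lactotropes and thyrotropes, Ikzf2 (0.06 ± 0.10), Prl (0.04 ± 0.15), Myc (-0.04 ± 0.14), Jag1 (-0.22 ± 0.19), Tshb (-0.28 ± 0.11) and Robo3 (-0.82 ± 0.30). Robo3 passed as lower under 6 settings, among them library totals (adjusted p = 0.0300, edgeR), the length and GC correction (log2 -1.06, 0.0327) and leaving out lysate 3 (-1.13, 0.0301), and Pou1f1 passed as enriched after the length and GC correction (0.48, 0.0171). Adjusted over the list alone, 9 rose and 2 fell, and the list as a whole had adjusted p = 0.649 with an estimated correlation (limma camera). Hoxa9 had 0 counts in all 10 libraries and was not tested. Whether part of this list was first chosen on these samples is not known here, so its count is not independent evidence of direction. Dcx lost its call without the lysate block (adjusted p = 0.118, edgeR), with library totals (0.0597) and without lysate 3, 5 or 7 (0.0829, 0.0545 and 0.0777), and Cdkn1a, Smad3 and Numb lost theirs without lysate 7 (0.0542, 0.0623 and 0.0589), which left 5 of the list higher. After the length and GC correction Smad3 and Mapt stood at 0.34 and 0.34.

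Among the hormone mRNAs Fshb alone was enriched. Prolactin (Prl), at 14333 ± 15173 CPM in IgG, and growth hormone (Gh, -0.19 ± 0.13), at 9707 ± 5085, were the most abundant of them and did not pass. Neither did Pomc (0.04 ± 0.10), the precursor of adrenocorticotropin, nor Cga (-0.07 ± 0.12), the alpha subunit shared by the glycoprotein hormones, nor Tshb, the beta subunit of thyrotropin. Of 6 hormones tested, 1 rose and 0 fell, as when adjusted over the list alone, with adjusted p = 0.916 with an estimated correlation; their median was -0.016 while their mean was 0.30. Lhb had 0 counts in all 10 libraries and could not be assessed. Tshb passed as lower under library totals (log2 -0.45) and under 4 other settings, and Gh under limma-voom (-0.34) and without lysate 6 (-0.29).

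**Figure D2:**
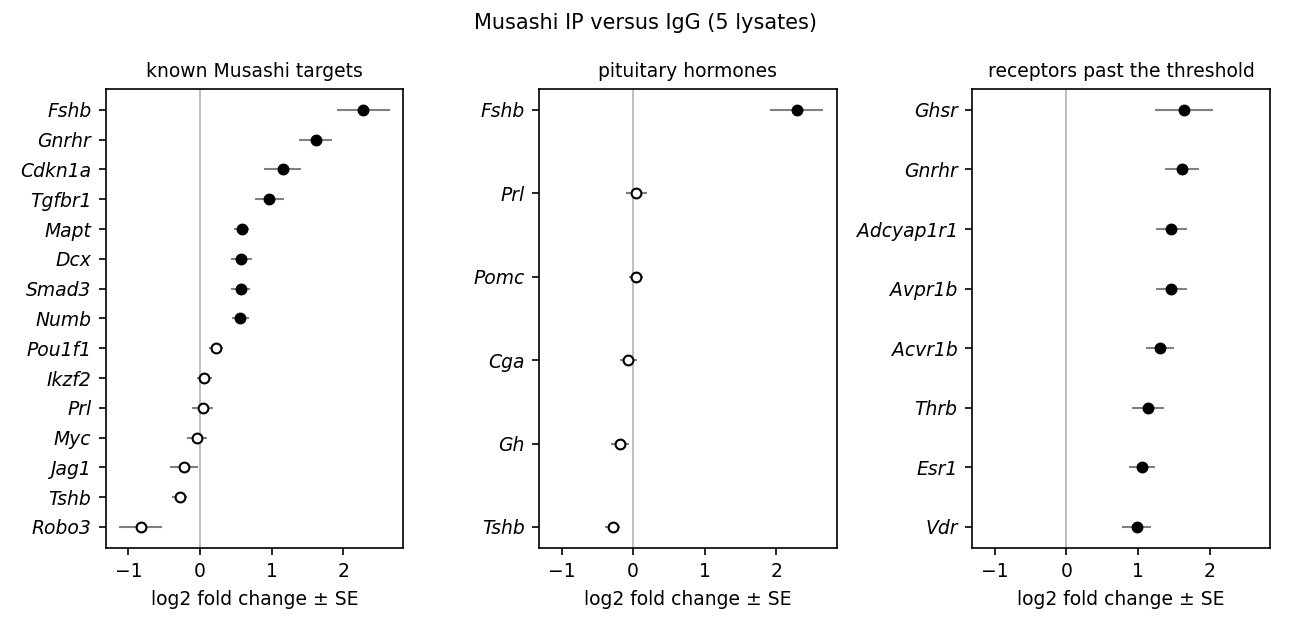
Log2 fold change ± SE of Musashi IP over IgG (5 lysates) for 15 of the 16 tested known Musashi targets (1 is not shown here), pituitary hormones and the receptors named from the 2 receptor lists, with filled points past adjusted p 0.05. Fshb (2.28) and Gnrhr (1.61) lie farthest to the right among the targets, and the other 5 hormones lie between -0.28 and 0.04.

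**Figure D3:**
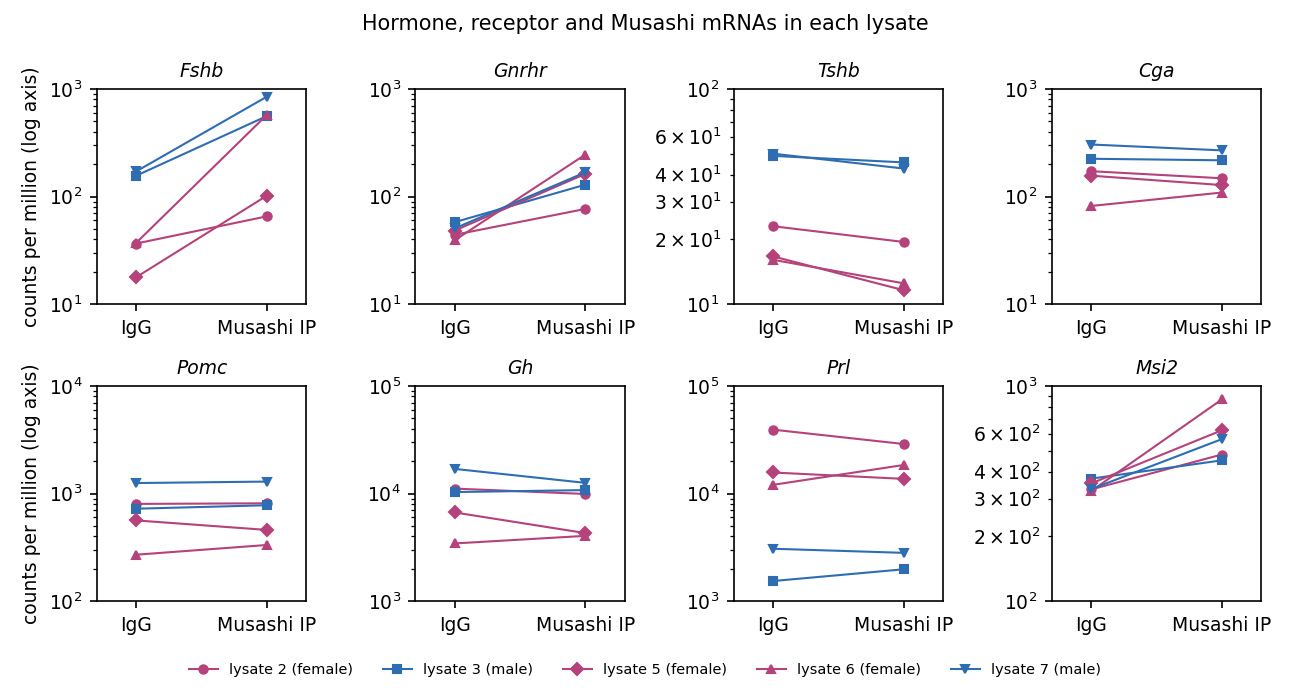
CPM (log axis) of hormone, receptor and Musashi mRNAs in the IgG and Musashi IP library of each lysate, joined by lines and coloured by sex. Fshb, Gnrhr and Msi2 rise in 5 of 5 lysates and Tshb lies lower in 5 of 5, while Prl is higher in Musashi IP in 2 of 5.

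Of 15 hypothalamic hormone receptors 12 rose and 0 fell, led by Ghsr (1.64 ± 0.41), the ghrelin receptor, Gnrhr, the PACAP receptor Adcyap1r1 (1.47 ± 0.22) and the vasopressin receptor Avpr1b (1.46 ± 0.22). Of 18 receptors for peripheral feedback signals 11 rose and 0 fell, led by the activin receptor Acvr1b (1.31 ± 0.20), the thyroid hormone receptor Thrb (1.14 ± 0.22), the oestrogen receptor Esr1 (1.05 ± 0.18) and the vitamin D receptor Vdr (0.98 ± 0.20). Adjusted over the list alone the counts were 12 and 12. Of 29 pituitary transcription factors 11 rose and 1 fell, with 15 and 1 adjusted over the list alone. They included Pitx1 (1.46 ± 0.21), Nr5a1 (1.37 ± 0.22), the gonadotrope factor, and Sox9 (1.24 ± 0.31). Each of these 3 lists had adjusted p = 0.649 with an estimated correlation. Ghsr lost its call without lysate 7 (adjusted p = 0.0776, edgeR) and Sox9 without lysate 5 or 7 (0.0549 and 0.0540). The count of higher hypothalamic receptors fell from 12 to 8 without lysate 5 or 7. It was 9 with library totals or without the lysate block, and 10 with DESeq2 size factors. Without lysate 7, 7 feedback receptors were higher, and the 1 lower transcription factor lost its call without lysate 2, 5 or 7 or the lysate block, which left 0 lower (edgeR).

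Of 28 granule genes 10 rose and 0 fell (12 and 0 adjusted over the list alone), with Rab27a (1.91 ± 0.24) and Rab27b (1.07 ± 0.14), which tether granules, Syt4 (1.70 ± 0.26), a synaptotagmin, and the prohormone-processing carboxypeptidase Cpe (1.22 ± 0.22). Of 13 stem or progenitor markers 5 rose and 0 fell (6 and 0 adjusted over the list alone), including Fstl1 (2.01 ± 0.29) and Ednrb (1.47 ± 0.37), which was lower in lysate 2 (-0.43) and lost its call without lysate 5 or 7 (adjusted p = 0.0549 and 0.0536, edgeR). Lactotrope markers had 4 higher of 6, among them Akr1c14 (1.28 ± 0.27), Angpt1 (1.18 ± 0.16) and the dopamine receptor Drd2 (0.82 ± 0.16). Gonadotrope markers had 3 higher of 7 (Fshb, Gnrhr and Nr5a1), corticotrope and melanotrope markers 3 of 7 (Avpr1b, Pax7 at 0.80 ± 0.14 and Crhr1 at 0.48 ± 0.14), somatotrope markers 3 of 8 (Pappa2 at 0.98 ± 0.20, Wnt10a at 0.90 ± 0.19 and Foxo1 at 0.88 ± 0.18) and thyrotrope markers 2 of 5 (the deiodinase Dio2 at 1.79 ± 0.22 and Trhr at 0.51 ± 0.17). No marker of these hormone cell types fell in the main fit, and adjusted over the list alone the counts were the same, except that 1 thyrotrope marker was then lower. The lists for granules, stem cells, lactotropes, gonadotropes and corticotropes with melanotropes had adjusted p = 0.649 with an estimated correlation, and those for somatotropes and thyrotropes 0.695. The somatotrope and thyrotrope medians were -0.05 and -0.04 while their means were 0.23 and 0.38, and the corticotrope and melanotrope median of 0.15 became -0.02 under library totals. With that scaling 2 granule genes, 1 gonadotrope marker and 1 thyrotrope marker passed as lower. Crhr1 and Trhr lost their calls with library totals (adjusted p = 0.0846 and 0.176, edgeR), Crhr1 also after the length and GC correction (0.0964) and without lysate 2, 5 or 7 (0.0514, 0.0774 and 0.115). Trhr also lost its call with DESeq2 (0.152), DESeq2 size factors (0.0548), no low-count filter (0.0794), the 2 CPM filter (0.0845), protein-coding genes only (0.0794), no lysate block (0.104) and without lysate 3, 5, 6 or 7 (0.158, 0.0911, 0.0884 and 0.224). Without lysate 7 the counts of higher members fell to 6 granule genes (also 6 without the block) and 1 stem or progenitor marker (3 without lysate 5), and 1 somatotrope marker passed as lower without lysate 6 and 1 granule gene without lysate 2.

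Markers of other cell types in the gland were lower or did not pass. Of 8 endothelial and 9 mural or fibroblast markers 0 rose and 0 fell, also when adjusted over the list alone, with medians of -0.38 and -0.37 (adjusted p = 0.763 with an estimated correlation for each); without lysate 2, 2 mural markers passed as higher, and without lysate 3, 1 endothelial and 5 mural markers passed as lower. Of 10 immune markers 2 fell, the leukocyte phosphatase Ptprc (-0.66 ± 0.16) and the macrophage receptor Csf1r (-0.47 ± 0.12). Of 5 erythroid markers 3 fell (Hbb-bs, Hbb-bt and Hba-a1 at -0.55 ± 0.14), or 4 adjusted over the list alone. Immune markers had 2 lower adjusted over the list alone, and both lists had adjusted p = 0.649 with an estimated correlation. All 5 of these calls were lost without the lysate block (adjusted p from edgeR 0.0621 for Ptprc, 0.188 for Csf1r, 0.0965 for Hbb-bs, 0.191 for Hbb-bt and 0.256 for Hba-a1). All but Hbb-bs were lost without lysate 5 as well (0.0633 for Ptprc, 0.150 for Csf1r, 0.103 for Hbb-bt and 0.0965 for Hba-a1), Csf1r, Hbb-bt and Hba-a1 without lysate 7 (0.0862, 0.0629 and 0.0573), and Hbb-bt without lysate 2 (0.0597). Posterior lobe markers had 0 of 4 past the threshold. With library totals 1 endothelial and 2 mural or fibroblast markers passed as lower.

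In the TGF-beta and activin pathway 14 of 24 members rose and 0 fell (15 and 0 adjusted over the list alone), including the ligand Tgfb3 (1.38 ± 0.19), Acvr1b, the activin and inhibin subunit Inhbb (1.24 ± 0.22) and the receptor Tgfbr2 (1.22 ± 0.33), whose call was lost without lysate 5 or 7 (adjusted p = 0.0659 and 0.0693, edgeR). In the Wnt pathway 9 of 25 rose and 1 fell (10 and 1 adjusted over the list alone), with the receptors Fzd1 (2.83-fold), Fzd7 (1.31 ± 0.25) and Fzd3 (0.95 ± 0.15) and the kinase Gsk3b (1.29 ± 0.19). Of 24 Notch pathway genes 7 rose and 0 fell (the same adjusted over the list alone), with Maml1 (0.65 ± 0.12) and the ubiquitin ligase Mib1 (0.65 ± 0.16). Their list p-values were adjusted p = 0.649, 0.649 and 0.695 with an estimated correlation. Without lysate 7 the number of higher Notch genes fell to 3 (4 without lysate 5 or without the block) and of Wnt genes to 5 (also 5 without lysate 3). Without lysate 3, 2 Notch genes and 1 TGF-beta gene passed as lower, and the lower Wnt call was lost without lysate 5, lysate 7 or the block. Maml1 stood at 0.41 after the length and GC correction. Under library totals the Notch median turned from 0.10 to -0.08 and the Wnt median from 0.18 to -0.00054, and 1 Notch gene passed as lower.

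Of 45 RNA-binding and translation control genes 17 rose and 1 fell (20 and 1 adjusted over the list alone), led by the translation inhibitor Eif4ebp2 (1.84 ± 0.24), Eif4g2 (1.14 ± 0.24), the helicase Ddx6 (1.08 ± 0.22) and Celf1 (0.98 ± 0.16). Of 20 unfolded protein response genes 6 rose and 0 fell (the same adjusted over the list alone), among them the chaperone Canx (1.66 ± 0.29) and the transcription factors Atf4 (1.44 ± 0.21) and Atf6 (1.01 ± 0.19). Of 23 cell cycle genes 8 rose and 0 fell (the same adjusted over the list alone), with the cyclins Ccnd2 (4.39-fold, 2.14 ± 0.27) and Ccnd1 (1.78 ± 0.28) and the inhibitor Cdkn1c (1.99 ± 0.39), all genes that control entry into the cell cycle. Of 16 immediate early genes 3 rose and 0 fell (the same adjusted over the list alone): Fosl2 (1.06 ± 0.21), Btg2 (0.72 ± 0.16) and Jun (0.71 ± 0.16). Each of these 4 lists had adjusted p = 0.695 with an estimated correlation (limma camera). Under library totals 3 RNA-binding, 3 unfolded protein response, 2 cell cycle and 1 immediate early genes passed as lower. Without lysate 7 the higher members fell to 10 RNA-binding genes (11 without lysate 3) and 5 cell cycle genes; the lower RNA-binding call was lost without lysate 5, lysate 7 or the block and became 2 without lysate 3 or 6.

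Of 10 nuclear long noncoding RNAs 0 rose and 5 fell (1 and 5 adjusted over the list alone; adjusted p = 0.649 with an estimated correlation): Xist, the imprinted RNA Kcnq1ot1 (-0.51 ± 0.12), Mirg (-0.43 ± 0.13), Malat1 (-0.39 ± 0.10) and Rian (-0.36 ± 0.08). Malat1, Mirg and Rian lost their calls without the lysate block (adjusted p = 0.161, 0.0647 and 0.0908, edgeR) and Kcnq1ot1 after the length and GC correction (-0.22, 0.117). Without lysate 5 the calls of Malat1, Mirg and Kcnq1ot1 were lost (0.144, 0.154 and 0.0839), and without lysate 7 those of Malat1 and Mirg (0.0964 and 0.0936). Rian lost its call both times, leaving 1 and 2 of the list lower, and Mirg stood at -0.28 without lysate 6. In this list 1 RNA passed as higher without lysate 2 or 6. Among 3 abundant noncoding RNAs, too few for a list test, Rnu12 (-0.77 ± 0.18) and Scarna2 (-0.46 ± 0.11) were lower, as when adjusted over the list alone, and lost their calls without the block (0.124 and 0.137) and without lysate 5 (0.0589 and 0.116), Scarna2 also without lysate 7 (0.0557) and Rnu12 after the length and GC correction (-0.34, 0.219). Of 84 ribosomal protein genes 4 rose and 7 fell, 0 either way adjusted over the list alone, with a median of -0.11; the largest was Rpl22 (1.27 ± 0.25), and 36 fell under library totals. Without lysate 3, 29 of them fell, without lysate 6, 23, without lysate 2, 1, and without lysate 5, lysate 7 or the block 0; those higher went to 2 without lysate 3 or the block and 1 without lysate 5 or 7. Of 89 nuclear oxidative phosphorylation genes 5 rose and 9 fell (2 and 0 adjusted over the list alone), with Sdhd (1.58 ± 0.26) and Ndufa10 (0.69 ± 0.15) among the enriched. Of these, 15 fell without lysate 3, 4 without lysate 2, 1 without the block and 0 without lysate 5 or 7, and 9 rose without lysate 2; with library totals 26 fell. The ribosomal and oxidative phosphorylation lists had adjusted p = 0.763 with an estimated correlation. Of 11 mitochondrially encoded genes 6 rose and 1 fell (7 and 2 adjusted over the list alone; adjusted p = 0.695 with an estimated correlation), with mt-Nd4 (1.25 ± 0.21) and mt-Nd6 (0.90 ± 0.17) higher and the transfer RNA gene mt-Tc (-1.19 ± 0.26) lower, a call lost after the length and GC correction (-0.49, adjusted p = 0.221, edgeR), which put mt-Nd6 at 1.55. Of these genes 3 rose without lysate 3 or 7 and 2 without the block, and 2 fell without lysate 3. Of 35 replication histone genes, a family of near-identical copies, 9 rose and 2 fell (9 and 4 adjusted over the list alone; adjusted p = 0.916 with an estimated correlation), led by Hist1h2ac (1.95 ± 0.32) and Hist1h1c (1.80 ± 0.34); their median of 0.07 became -0.11 under library totals, where 10 fell. Without lysate 3, 6 histone genes fell, and without lysate 5 or 7, 0.

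Camera at the preset correlation of 0.01 called 16 of the 28 lists (smallest adjusted p = 6.88e-06). With an estimated correlation it called 0 (smallest adjusted p = 0.649, 0 lists at an unadjusted p under 0.05), and fry, which tests whether a list's genes move one way on balance, called 0 (smallest adjusted p = 0.0627, 16 lists at an unadjusted p under 0.05). No statement on a list above therefore rests on more than its count of members. The estimated correlation leaves little power with so few libraries. Between the sexes it did not call the list of Xist and 4 Y-linked genes, all of which passed singly. That list had adjusted p = 0.0810 in IgG and 0.104 in Musashi IP (limma camera, estimated correlation). The high list p-values above are thus not evidence that a list did not move. For comparison, 25.7% of all tested protein-coding genes rose and 4.01% fell. Counts such as 7 of 24 Notch, 6 of 20 unfolded protein response and 3 of 16 immediate early genes higher lie near or below that share. They show no excess of their own.

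Enriched mRNAs carried slightly denser Musashi motifs in their 3' UTRs. The 3627 enriched genes held 1.84 motifs per kb and the 10032 other tested genes 1.72 per kb after matching on 3' UTR length, GC content and mean expression, a difference of 0.127 per kb or 7.39% (permutation p = 1e-05, two-sided, the smallest that 100000 resamples can give; genes are not independent replicates). The UAG core alone was denser by 5.25% (permutation p = 1e-05). Shuffled motifs of the same composition were denser by 2.04% (permutation p = 0.00289). In coding sequence the motif was not denser, with a difference of -0.0187 per kb (permutation p = 0.293).

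The share of enriched genes rose with 3' UTR length. It was 3.92% in the 20% of genes with the shortest 3' UTRs, 17.5%, 27.9% and 36.1% in the next 3 bins of equal number and 47.3% in the bin with the longest, while the share of lower genes went from 6.44% to 2.42%. Enriched genes had a median 3' UTR of 2076 nt and other tested genes of 995 nt. Across 13659 genes the log2 fold change correlated with 3' UTR length at a Spearman rho of 0.4002. Annotated 3' UTRs were 1140 nt for Fshb and 1655 nt for Gnrhr, against 72 nt for Tshb, 95 nt for Gh, 155 nt for Prl, 174 nt for Pomc and 227 nt for Cga. Single genes also went against the trend: Ikzf2, with 7554 nt and 16 motifs, stood at log2 0.06, Jag1, with 1568 nt, at -0.22, and Atf4, with 81 nt, rose 2.71-fold. Tshb, Gh and Atf4 lie under the 100 nt minimum, so they are not among the 13659 genes or in the bins.

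**Figure D4:**
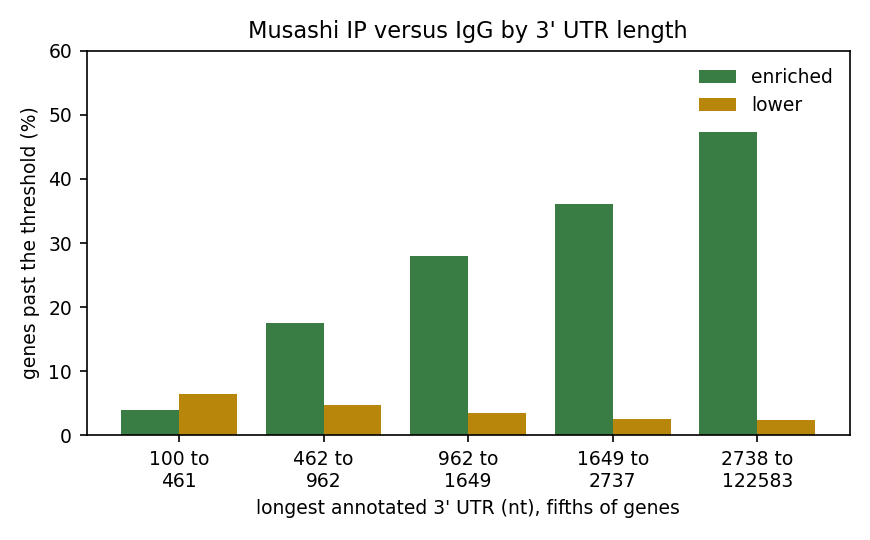
Percentage of tested genes enriched (green) or lower (brown) in Musashi IP, for 5 bins of genes by the length of the longest annotated 3' UTR in nucleotides. The enriched share goes from 3.92% to 47.3% and the lower share from 6.44% to 2.42%.

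Among the 10 most enriched RNAs named above, Tmem167b again had the largest value within females (3.13 ± 0.44, n = 3 lysates). In females 2383 genes were enriched and 357 lower (edgeR, Benjamini-Hochberg 0.05), with 6905 at an unadjusted p under 0.05. Within males Tmem167b stood at 2.53 ± 0.52 (n = 2 lysates) and 0 of 20550 genes passed by edgeR, with 2548 at an unadjusted p under 0.05, 544 past the threshold by DESeq2 and 2895 by limma-voom. The fit shares 1 estimate of spread over all 10 libraries. The male SE and count therefore do not measure scatter among the male lysates alone. Leaving out lysate 6 or lysate 2, both female, took the male count by edgeR to 1852 or 1307. Of the genes enriched in females, 2367 (99.3%) also lay above 0 in males, with medians of log2 1.20 in females and 0.82 in males, and 346 of the 357 lower genes (96.9%) lay below 0. Both sets were chosen for passing in females, which by itself moves their female values farther from 0 than the male ones. Over all tested genes the median male log2 fold change was -0.020. Female and male fold changes correlated across the 20550 genes at Pearson's r = 0.790 and Spearman's rho = 0.745; genes are not independent replicates. The female count depends on single lysates, with 0 genes without lysate 5 by edgeR (4577 at an unadjusted p under 0.05) and 5836 without lysate 2; with library totals 2235 were enriched and 1588 lower.

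No gene's antibody effect differed between the sexes past the threshold. The 5 genes of smallest p, none passing, were Ank1 (female minus male log2 0.84 ± 0.24), C2cd4c (1.18 ± 0.36), the myosin gene Myh9 (-0.62 ± 0.19), Erfe (0.86 ± 0.27) and the basement membrane collagen gene Col4a2 (-1.18 ± 0.38). The edgeR test of the difference called 0 genes (187 at an unadjusted p under 0.05; smallest Benjamini-Hochberg adjusted p = 1), as did DESeq2 (50) and limma-voom (1762). In simulated counts this test found 35% of genes with a 3-fold difference, so a difference of that size can be missed. Of the 28 lists, camera called 7 at the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.903; 0 lists at an unadjusted p under 0.05), and fry called 0 (0.915; 0 lists at an unadjusted p under 0.05). The median difference was -0.93 for endothelial and -0.59 for mural markers.

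**Figure D5:**
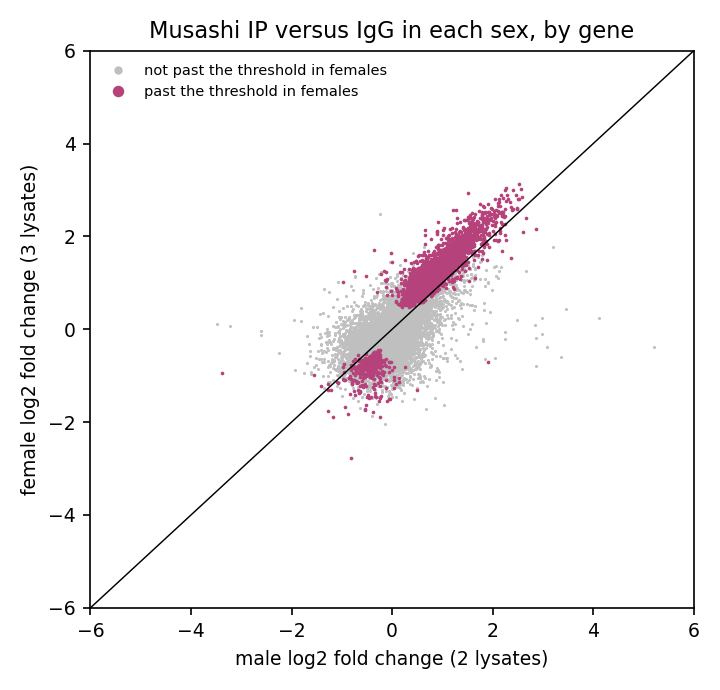
Log2 fold change of Musashi IP over IgG in males (horizontal axis, 2 lysates) and females (vertical axis, 3 lysates), with 1 point per gene and the line of equal values. Genes past the threshold in females (coloured) lie mostly on the same side of 0 in males, as 2367 of 2383 enriched genes do.

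Comparing the sexes within IgG libraries gives the background RNA of each sex. Prolactin was 23672 ± 15587 CPM in 3 female libraries and 2453 ± 1150 in 2 male ones (log2 3.27 ± 0.52), while Fshb (-2.43 ± 0.26) and Tshb (-1.42 ± 0.20) were higher in males. The secreted protein gene Reln (6.83 ± 0.33), the corticotropin-releasing hormone binding protein gene Crhbp (8.00 ± 0.59; 565 to 1062 counts per female library, 0 and 6 in the male ones), the relaxin receptor gene Rxfp1 (7.25 ± 0.46) and Adamts19, a metalloproteinase gene, were higher in females; Adamts19 had 0 counts in both male libraries and was at least 69.0-fold higher, taking 3 counts per library as the floor. Loxhd1, a gene of sensory hair cells, was higher in males (-3.83 ± 0.40). Y-linked Ddx3y and Eif2s3y, with 0 counts in the female libraries, were at least 381-fold and 334-fold lower there. Msi1 (0.03 ± 0.23) and Msi2 (-0.07 ± 0.16) did not pass. Tshb lost its call without IgG 3 or IgG 7 (adjusted p = 0.0642 and 0.0624, edgeR).

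Of the lists, hormones had 1 member higher in females and 2 lower of 6 tested (1 and 5 adjusted over the list alone), and Gh (-0.95 ± 0.39), Pomc (-0.87 ± 0.36) and Cga (-0.96 ± 0.27) did not pass over all genes. Cga passed as lower in females under 7 settings, including DESeq2 (adjusted p = 0.0214), library totals with edgeR (0.0244), limma-voom (0.0110) and leaving out IgG 2 or IgG 5 (0.0106 and 0.0394). Gh and Pomc passed with limma-voom (0.0109 and 0.0301), without the low-count filter (4.56e-07 and 5.09e-05, edgeR) and without IgG 2 (0.00651 and 0.0185). Lactotrope markers had 2 higher, Prl and the steroid dehydrogenase Akr1c14 (4.29 ± 0.38), and 1 lower, the angiotensin receptor Agtr1a (-3.36 ± 0.29), of 6 (3 and 1 adjusted over the list alone). Among feedback receptors the progesterone receptor Pgr (2.87 ± 0.25) and Igf1r (0.82 ± 0.18) were higher in females and Vdr (-1.14 ± 0.27) lower. Hypothalamic receptors had Oxtr (4.59 ± 0.92) higher and Ghrhr (-1.29 ± 0.22) lower in females. The transcription factors Neurod4 (1.49 ± 0.26) and Tcf7l2 (1.34 ± 0.26) were higher and Gata2 (-1.34 ± 0.28) lower. Ribosomal protein genes had 0 of 83 past the threshold, with a median of 0.69, and endothelial markers 0 of 8, with a median of 1.17, while the collagen gene Col1a2 (1.45 ± 0.23) was higher among 9 mural markers. Without IgG 3 the calls of Prl, Igf1r, Vdr, Oxtr, Ghrhr, Neurod4, Tcf7l2, Gata2 and Col1a2 were lost (adjusted p from edgeR 0.151, 0.0758, 0.296, 0.227, 0.135, 0.167, 0.101, 0.286 and 0.131). Without IgG 7 those of the same genes except Ghrhr were lost (0.0728, 0.247, 0.1102, 0.264, 0.131, 0.237, 0.0845 and 0.0603). Igf1r and Vdr were also lost without IgG 5 (0.0602 and 0.0760) or IgG 6 (0.0527 and 0.0812), and Igf1r with library totals (0.0722).

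In total 558 genes were higher in females and 387 in males (edgeR, unpaired, Benjamini-Hochberg 0.05; 3493 at an unadjusted p under 0.05), and with library totals 541 and 556. The count depends on IgG 3 and IgG 7: without IgG 3 the count fell from 945 to 172 genes and without IgG 7 to 195, a single male library then being assumed to vary like the females, and Prl lost its call both times.

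Within Musashi IP libraries the same comparison showed Prl (3.09 ± 0.45), Reln (7.52 ± 0.40), Crhbp (8.64 ± 0.49; 870 to 1290 counts per female library, 1 and 5 in the male ones) and the cholecystokinin receptor gene Cckar higher in females, Cckar with 209 to 319 counts per female library and 0 or 1 per male library. Tshb (-1.61 ± 0.28), Agtr1a (-3.28 ± 0.31) and Loxhd1 (-3.81 ± 0.37) were higher in males. Pgr (2.85 ± 0.26), Oxtr (5.14 ± 0.61), Akr1c14 (4.89 ± 0.53), Neurod4 (1.83 ± 0.26) and the transcription factor gene Fosl2 (2.47 ± 0.29) were higher in females. Fshb, at 224 ± 251 CPM in females and 667 ± 184 in males, did not pass (-1.57 ± 0.70; adjusted p = 0.296, edgeR with Benjamini-Hochberg), and passed without Musashi IP 6 (-3.06; 0.000438), with limma-voom (-2.58; 0.00488) and without the low-count filter (-1.57; 1.92e-06). Tshb lost its call without Musashi IP 5 (0.104), and Neurod4 without Musashi IP 3 or 5 (0.0683 and 0.0538). Hormones had 1 member higher and 1 lower of 6 (1 and 2 adjusted over the list alone), and lactotrope markers 2 and 1 of 6, as when adjusted over the list alone.

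In total 403 genes were higher in females and 201 in males in Musashi IP (edgeR, unpaired, Benjamini-Hochberg 0.05; 3505 at an unadjusted p under 0.05), with 376 and 386 under library totals. Without Musashi IP 5 the count fell from 604 to 219, without Musashi IP 3 to 315 and without Musashi IP 7 to 322, and it rose to 999 without Musashi IP 2. Of 20446 genes tested in both antibody groups, 551 and 385 were higher in females, 328 of them in both, against 10.4 for independent lists, and 382 and 196 were higher in males, 150 in both, against 3.66. The libraries of both comparisons come from the same lysates, so part of this overlap follows from the shared animals.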

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

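All values in this part come from tests fixed before the data were examined, and a test for a sample far from its group picks out about 1 group in 20 by chance. It found 10 of 143 groups of 5, where chance gives 7.15. Of the IgG libraries, IgG 2 lay far from the other 4 in its TMM factor (0.956, others 1.08 to 1.11), its share of TEC loci (1.94%, others 3.03 to 3.11%) and its share of pseudogenes (0.765%, others 0.933 to 0.976%). IgG 2 also stood apart in its share of mitochondrial genes (2.77%, others 0.210 to 0.798%) and of genes without an annotation match (4.05%, others 1.85 to 2.48%). These 5 measures, a scaling factor and 4 shares, come from the same library, so they are not independent of each other.

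Among named genes, 1 lysate lay far from the other 4 in the log2 ratio of Musashi IP over IgG for 5 genes. For the alpha-globin gene Hba-a1 lysate 3 stood at 0.077 (others -0.84 to -0.62), and for the Notch effector Heyl lysate 2 stood at -0.37 (others 0.83 to 1.29). Lysate 6 stood apart for the transcription factor gene Fosl2 (2.14, others 0.55 to 0.98), for Kcnq1ot1 (-1.06, others -0.46 to -0.23) and for Malat1 (-0.85, others -0.37 to -0.19).

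For 7 gene lists the antibody effect differed between females and males by camera at the preset correlation, each lost with an estimated correlation (smallest adjusted p = 0.903 over all lists). As median female minus male log2 effects these were 0.23 for pituitary transcription factors, -0.93 for endothelial markers, -0.59 for mural and fibroblast markers, 0.15 for RNA-binding and translation control genes, 0.22 for unfolded protein response genes, 0.40 for immediate early genes and -0.36 for mitochondrially encoded genes.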

How the results depend on the processing

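The setting with protein-coding genes only was chosen after the data were seen, and the others before. The count of 5531 genes in Musashi IP against IgG stayed within 1.5 times under every setting that kept all libraries. Of the named genes past the threshold in the main fit, 0 reversed direction in any gene-level comparison. Changes of sign in named genes that did not pass were not counted. The number of lower genes moved from 1727 to 4107 with library totals, 3397 with limma-voom, 3214 with a filter of at least 2 CPM and 670 without the lysate block. The block rests on the pairing of libraries. Correlation of deviations from the group means within a lysate's own pair was 0.523, 0.679, 0.602 and 0.778 for lysates 2, 3, 5 and 7. These values were above those of the IgG library with the Musashi IP library of any other lysate. For lysate 6 the value was 0.186, below its highest other of 0.415. Counts within females moved to 9176 with limma-voom and 4393 without the low-count filter, and within males from 0 to 544 with DESeq2, 2895 with limma-voom and 1489 without the filter. Between the sexes the count moved to 1947 in IgG without the filter, and in Musashi IP to 1059 with DESeq2, 1266 with limma-voom and 1679 without the filter. Gene lists past the threshold went from 16 to 8 with protein-coding genes only, 10 with the length and GC correction, 0 with an estimated correlation and 0 with fry, and for the sex difference from 7 to 1 without the filter, 0 with an estimated correlation and 0 with fry. The motif difference turned to -0.0187 per kb in coding sequence. Leaving out 1 lysate or library at a time gave 2885 to 5978 genes for Musashi IP against IgG (2288 to 4188 enriched, 182 to 2100 lower), 0 to 5836 within females, 0 to 1852 within males and 0 to 0 for the sex difference. It gave 172 to 1354 genes between the sexes in IgG, 219 to 999 in Musashi IP, 13 to 16 gene lists and 1 to 10 lists for the sex difference. For all of these the cause was not tested.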

Other observations

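In this part, the tests of coding sequence length, of motif density against shuffled orders and of the split count for gene lists were chosen after the result was seen. The gene with the identifier ENSMUSG00002076161, which has no match in the annotation used, held 1.90 ± 0.560% of IgG counts and 0.939 ± 0.411% of Musashi IP counts (n = 5 each) and was lower in 5 of 5 pairs. It was chosen after its share was seen.

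Noncoding loci inside introns did not rise with enriched host mRNAs. Those hosts were picked for being enriched, which by itself puts their median above 0. For 336 such loci in hosts enriched in Musashi IP, the hosts had a median log2 fold change of 0.66 and the loci one of -0.43, with 327 of the loci (97.3%) below 0, 100 lower past the threshold and 0 enriched (edgeR). In hosts that were not enriched, 1067 loci had a median of -0.47.

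Enrichment rose with 3' UTR length. Fold change fell with coding sequence length (Spearman rho -0.257), so the length of the coding part does not explain the rise. Total transcript length was not set against fold change, so it stays open as a cause. GC content of the 3' UTR is argued against, since within 5 bins of it the lowest rho with 3' UTR length was 0.359. The number of Musashi motifs may contribute: the matched difference between enriched and other genes was larger for Musashi motifs than for a shuffled order, by 0.0776 per kb. It is argued against as the whole cause, since rho was 0.4003 among 3653 genes with 0 motifs in the 3' UTR. What else goes with 3' UTR length, such as sites this motif misses or other proteins, stays open and was not tested.

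Of the 1727 genes lower in Musashi IP, 592 were TEC loci, 569 protein-coding, 298 long noncoding, 154 pseudogenes and 70 small noncoding; the explanations here concern TEC and intronic loci. GC content and length are argued against as the whole cause, since TEC loci lay 0.42 below protein-coding genes of the same length and GC (difference -0.42, 1679 loci). As part of the cause they stay open, since the length and GC correction took the difference from -0.53 to -0.27. Less unspliced nuclear RNA in Musashi IP than in IgG is a hypothesis that the intronic loci cannot decide. Their median of -0.43 was below 0 in all 5 lysates, but they are TEC and long noncoding loci. Medians of those whole classes, -0.44 and -0.28, were also below 0 in all 5 lysates. Intronic loci in hosts that were not enriched stood at -0.47. Because counts are relative, a gain in bound mRNA lowers every other RNA, so a loss cannot be read from these values.

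The size of the enrichment differed between lysates, with medians over the 3804 enriched genes of 0.45, 0.51, 0.87, 1.57 and 0.81 for lysates 2, 3, 5, 6 and 7. Sequencing depth is argued against, since the gap between the largest and smallest was 1.12 and stayed at 1.10 after thinning to equal totals. Sex is argued against as the whole cause, since 2 of 2 male lysates lay inside the female range. That range spans the lowest and highest of all 5 lysates, so sex as part of the cause stays open. Differences between occasions in the immunoprecipitation stay open as a possible explanation and were not tested.

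For the 5531 genes past the threshold, 2 of 100 splits of the 10 libraries gave as many genes, the real one included. These 2 were also the only splits that gave any gene. The lysate stayed as a block in each fit, so a split drew only on the pairs that it parted. Splits that left pairs together had less to draw on, so the low share does not exclude chance. The highest other split gave 5769 genes, and it follows the antibody in lysates 5, 6 and 7 while leaving lysates 2 and 3 unparted. Among the 16 splits that part every pair, the real one gave 5531 genes and the highest other 0, with 1 split as large, and 16 are too few for a share under 0.05. Within females 1 of 10 splits gave as many as the real 2740 genes, with a highest other of 0, and 10 are too few as well. For the preset camera lists 16 of 100 splits gave 16 or more lists, the highest other 19, so chance cannot be excluded.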
